A study of Mus musculus with 8 samples.

How the data were processed

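Whole mouse embryos were measured in pools by RNA-seq, in 8 libraries that fall into 4 groups of 2 by oocyte genotype and stage. Per the labels' protocols, oocytes came from superovulated females of 2 kinds. Wild-type females are given as f/f, homozygous for the floxed Tet3 allele, and the labels do not say whether they carried Cre. The other females carried a floxed and a null Tet3 allele with a Zp3-Cre transgene, which is active in growing oocytes. Their oocytes, and the embryos made from them, are called Tet3-null here. All oocytes were fertilized in vitro with sperm of the CAST/EiJ strain, and zygotes with 2 pronuclei were cultured. The name Tet3-null refers to the oocyte, since the embryos also received a Tet3 allele from the sperm. Pools of 10 embryos were taken at the 2-cell stage, 30 h after fertilization, and pools of 7 at the blastocyst stage, at 96 h. Lysed embryos were converted to amplified cDNA with a SMARTer low-input kit, sheared, and made into libraries with a kit that does not mark strand. Reads of a gene and of its antisense partner, such as Xist and Tsix, therefore cannot be told apart.

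The deposited values are FPKM, fragment counts scaled by gene length and by the mapped total of the library, for 23234 genes in each library. The authors made them with TopHat2 2.0.10, Bowtie2 2.1.0 and Cufflinks 2.2.0 on the mouse build mm9, per the submitters' processing notes. The gene annotation, the settings and the treatment of reads shared by near-identical genes are not given in the sources used here. Values of gene families with close copies, such as Zscan4, Obox, Usp17l and Omt2, are uncertain for that reason. No coordinates are given, because the gene table at hand is of another build (GRCm38.p6). It was used only for gene names, for X and Y assignment and for the class of small RNA genes, and 22991 of the listed names matched a symbol in it.

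Read totals are unknown. The summed FPKM per library ranged from 600495 to 956335. Because a low value is a whole multiple of what 1 read is worth for that gene, the commonest ratio of values under 0.15 FPKM between libraries of a stage estimates their relative depth. Relative to wild-type replicate 1 of the stage, depth was 1.102 in wild-type replicate 2, 1.223 in Tet3-null replicate 1 and 1.014 in Tet3-null replicate 2 at the 2-cell stage. It was 1.133, 1.301 and 1.283 in the same order at the blastocyst stage. The peak of ratios was weakest for Tet3-null 2-cell replicate 2, at 8.5 times the median window against 37.3 and 47.3 for the other 2 libraries compared at that stage. FPKM of short genes is unstable, and small RNA genes held 7.23% to 12.8% of the summed FPKM. None of 8 housekeeping genes checked was listed at 0 in any library. Within groups no pair of libraries shared identical values other than 0.

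The main analysis took log2(FPKM + 1) of the 13549 genes with at least 1 FPKM in at least 2 libraries. All 8 libraries were fitted together with 4 group means in limma 3.58.1 (R 4.3.3), with empirical Bayes moderation and an intensity trend (4 residual and 3.07 prior degrees of freedom). Tests were two-sided, Benjamini-Hochberg adjustment ran over all genes tested, and genes were called at an adjusted p of 0.05. All adjusted p-values of single genes come from this limma test. Fold changes on the log2(FPKM + 1) scale understate the change of weakly expressed genes; ratios of mean FPKM are given beside them. A permutation test of 2 libraries against 2 cannot reach 0.05 and was not used. The comparisons were Tet3-null against wild-type at each stage, the difference of these effects between stages, and blastocyst against 2-cell in each genotype. A second count took genes whose mean log2(FPKM + 1) differed by at least 1 with no overlap between groups, with the same count for the 2 other splits of the 4 libraries.

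The test, the comparisons, the gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. The 19 lists, written from textbook knowledge, held 682 entries, of which 8 were not matched to a listed gene and 7 were matched by a synonym. They covered oocyte and maternal-effect genes, 2-cell-stage genes linked to Zscan4 and MERVL, ribosome biogenesis and early embryonic transcription, epiblast, primitive endoderm and trophectoderm genes, imprinted genes, germline genes under promoter methylation, DNA methylation machinery, chromatin modifiers, DNA replication, mitosis, glycolysis, p53 targets and apoptosis, interferon genes, X inactivation and Y-linked genes, and markers of cumulus and granulosa cells, of sperm, and of blood and other somatic cells. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 19 lists, and again with an estimated correlation. Counts of list members were also adjusted over the list alone.

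Named genes were taken by rule: Tet3, Tet1, Tet2, Dnmt1, Dnmt3a, Dnmt3b, Dnmt3l, Uhrf1, Dppa3 and Tdg; per genotype comparison, the called genes without overlap between groups with the 12 largest rises and 12 largest falls, filled to 10 by unadjusted p where fewer than 10 of a direction were called; the 8 smallest p-values for the difference between stages; the 10 largest rises and falls of the wild-type stage effect; and the 3 leading members of each list described. Unnamed gene models and small RNA genes were passed over but counted. Genes named outside the rule are said to be chosen after their values were seen.

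The fit was tested on simulated data for the 13549 genes drawn with independent normal noise, the observed wild-type means and the moderated spreads. For the 2-cell comparison it recovered 27 of 100 genes changed by 1 on the log2 scale and 90 of 100 changed by 2, with 4 false calls. For the blastocyst comparison it recovered 34 and 95, with 6 false calls, and for the difference between stages 8 and 66, with 5 false calls. With no change simulated it called 0 genes in each comparison. Each gene had the same spread in all simulated groups. The simulation therefore does not cover groups that differ in spread or a library that stands apart. A list shifted by 0.5, that of oocyte and maternal-effect genes, was called in each comparison and 0 other lists were. As the simulated noise was independent between genes, this does not cover lists whose members vary together. The estimated inter-gene correlation of that list in the data was 0.292.

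The alternatives chosen beforehand were a pseudocount of 0.1, no filter, a filter at 5 FPKM, quantile normalization, median-of-ratios scaling, a fit on the libraries of a comparison alone, robust moderation, the replicate number as a block, an estimated correlation for lists, and leaving out each library in turn. Where a library is left out, the remaining one is assumed to vary like the other groups. Alternatives added after seeing the data left out small RNA genes, left out X-linked and Y-linked genes, and estimated the spread without Tet3-null 2-cell replicate 2. Follow-up tests and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.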

Results

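Transcript levels were measured in mouse embryos from wild-type and Tet3-null oocytes, at the 2-cell stage and at the blastocyst stage, with 2 libraries in each of the 4 groups. Tet3 is the dioxygenase that oxidizes 5-methylcytosine in the zygote, and the comparison asked what its loss from the oocyte changed in the transcriptome of the embryo. Between 10607 and 11660 genes reached 1 FPKM per library. The 2-cell libraries had 11660 and 11576 such genes in wild-type and 10976 and 10954 in Tet3-null, and the blastocyst libraries had 10607 to 10794. Read totals are unknown. Values are mean FPKM ± SD of 2 libraries unless stated otherwise. The labels do not say that libraries of a group came from separate females or collections, so p-values measure only the spread between these samples, which may be technical.

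Libraries of a group were similar across genes, with Pearson's r of log2(FPKM + 1) of 0.963 for wild-type and 0.943 for Tet3-null 2-cell libraries, and of 0.977 and 0.982 for wild-type and Tet3-null blastocysts. Tet3-null 2-cell replicate 2 stood apart. Its r with the wild-type 2-cell libraries was 0.931 and 0.926, against 0.956 and 0.958 for replicate 1, and 7101 genes were listed at 0 in it, against 5549 to 6080 in the other 2-cell libraries.

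Tet3 itself was 2.38-fold lower in Tet3-null 2-cell embryos, at 3.85 ± 0.795 FPKM against 9.16 ± 2.30. The single libraries had 3.28 and 4.41 FPKM in Tet3-null and 10.8 and 7.54 in wild-type. The log2 change was -1.06 (SE 0.25) with an adjusted p of 0.0690 over all genes and of 0.0295 adjusted over the list alone, the list of methylation machinery. The labels do not say which exons the conditional allele removes, so FPKM over the whole gene can include the remaining part. The embryos also carry a Tet3 allele from the sperm, which can be transcribed after genome activation. FPKM over the whole gene does not separate these sources. In blastocysts Tet3 was at 0.465 ± 0.0759 and 0.708 ± 0.352 FPKM, which did not differ beyond the spread. Tet1 was at 2.02 ± 0.103 against 3.77 ± 0.170 FPKM in 2-cell embryos (adjusted p = 0.0929, and 0.0371 adjusted over the list alone) and at 6.77 ± 0.0455 against 6.47 ± 1.22 in blastocysts. Tet2 was at 1.22 ± 0.274 against 1.11 ± 0.0752 FPKM and at 46.6 ± 0.0463 against 55.0 ± 8.32 at the 2 stages, with no call.

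Dppa3, which encodes the Stella protein that protects maternal methylation in the zygote, rose 1.47-fold in Tet3-null 2-cell embryos, from 16623 ± 472 to 24381 ± 1662 FPKM (log2 change 0.55, adjusted p = 0.0471). It was the only member of the machinery list called over all genes, and the call was lost under quantile normalization (adjusted p = 0.403), with a pseudocount of 0.1 (0.0747), with no filter (0.272) and in the 2-cell libraries alone (0.516). It was also lost without Tet3-null replicate 2 (adjusted p = 0.0537), wild-type replicate 1 (0.136) or wild-type replicate 2 (0.134). Of the 33 members tested at the 2-cell stage, 2 were higher and 5 lower when adjusted over the list alone. The higher ones were Dppa3 and Mbd1, and the lower ones included Tet3, Tet1, Gadd45g and Idh2. Gadd45g, implicated in DNA repair and demethylation, was at 23.9 ± 0.424 against 41.7 ± 1.83 FPKM. Among the Dnmt genes, Dnmt1 was at 7.06 against 7.58 FPKM, Dnmt3a at 9.89 against 10.8, Dnmt3b at 3.31 against 4.34 and Dnmt3l at 29.65 against 32.05. Uhrf1, the cofactor of Dnmt1 at replicating DNA, was at 24.9 against 26.9, and none of these was called. The sign of these differences flipped under quantile and median-of-ratios scaling for Dnmt1, Dnmt3a, Dnmt3l and Uhrf1. Tdg, the glycosylase of oxidized cytosine, was near 0 FPKM in all 2-cell libraries. The list as a whole was not called at either stage (2-cell: median log2 change -0.16, adjusted p = 0.721; blastocyst: -0.05, adjusted p = 0.607).

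**Figure D1:**
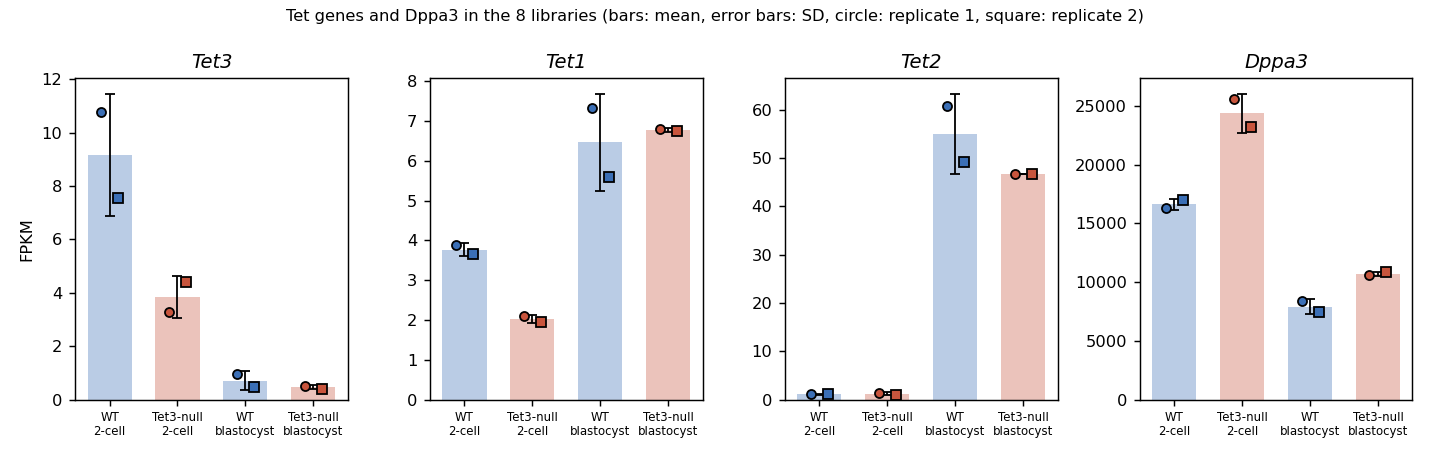
Mean FPKM (bars) with SD (error bars, 2 libraries) of Tet3, Tet1, Tet2 and Dppa3 in the 4 groups, with each library as a point. Both Tet3-null 2-cell libraries lay below both wild-type libraries for Tet3 (3.28 and 4.41 against 10.8 and 7.54 FPKM), while Tet2 rose to 46.6 and 55.0 FPKM in blastocysts.

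At the 2-cell stage, 368 of 13549 genes were called, 83 higher and 285 lower in Tet3-null embryos. The beta-defensin gene Defb13 was at 7.77 ± 1.62 FPKM in Tet3-null and listed at 0 in both wild-type libraries (log2 change 3.12, SE 0.18, adjusted p = 0.00138). The galectin genes Lgals1 and Lgals3 fell 5.11-fold and 6.16-fold, from 135 ± 12.4 to 26.4 ± 3.95 FPKM and from 19.9 ± 1.91 to 3.24 ± 0.479 (adjusted p = 0.00707 for each). Gata2, a transcription factor of the trophectoderm and of blood, fell 3.95-fold, from 30.2 ± 2.07 to 7.66 ± 1.31 FPKM (adjusted p = 0.00839). The calls included 8 small RNA genes and 56 unnamed gene models.

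Other genes that rose were Ddhd1, a phospholipase, at 63.3 ± 14.2 against 18.3 ± 0.842 FPKM (3.45-fold), Tac2, the precursor of neurokinin B, at 82.7 ± 29.1 against 26.3 ± 3.41 (3.15-fold), and Schip1, a partner of the tumor suppressor schwannomin, at 29.1 ± 4.74 against 6.86 ± 2.90 (4.24-fold). Fgl1, a fibrinogen-related secreted protein, rose 4.37-fold from 2.54 ± 0.184 to 11.1 ± 0.931 FPKM (adjusted p = 0.0229), and Selp, the adhesion molecule P-selectin, was at 11.1 ± 5.27 against 2.56 ± 0.156. Weakly expressed risers were Batf3, Epdr1 and E2f6, with a mean below 1 FPKM in wild-type, and Sprr2e, Myl2 and Hist2h2ac, listed at 0 in wild-type.

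Among genes that fell, Kcne3, a potassium channel subunit, dropped 10.4-fold from 15.5 ± 2.25 to 1.497 ± 0.670 FPKM (log2 change -2.75, SE 0.23, adjusted p = 0.00707). The homeobox gene Lbx2 was at 2.90 ± 2.81 against 21.99 ± 8.11 FPKM and the neutrophil protease gene Prtn3 at 2.78 ± 1.62 against 18.1 ± 2.32. Cypt12 was at 2.35 ± 1.22 against 14.1 ± 2.19. Coro1a, an actin-binding coronin, Prph, the intermediate filament peripherin, Cox7b2, a cytochrome oxidase subunit, Fabp6, a bile acid-binding protein, and Tnni2, a muscle troponin, were all below 1 FPKM in Tet3-null embryos and at 3.77 to 5.61 in wild-type.

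**Figure D2:**
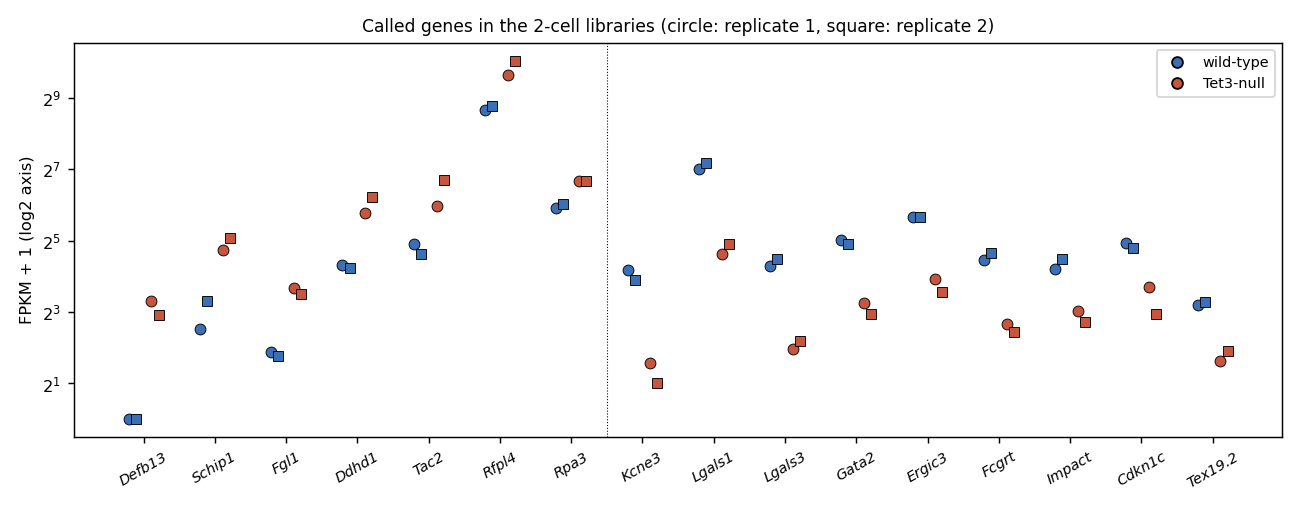
FPKM + 1 on a log2 axis of 16 called genes in the 4 2-cell libraries, one point per library, with 7 higher genes left of the dotted line and 9 lower genes to its right. Wild-type and Tet3-null points do not overlap for any gene shown, with Defb13 listed at 0 in wild-type and Lgals1 at 135 against 26.4 FPKM.

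The balance of higher and lower calls depended on scaling. Under the deposited scaling the median log2 change of all genes at the 2-cell stage was -0.17. Median-of-ratios scaling, which sets that median to 0, gave 83 higher and 80 lower genes, and quantile normalization gave 88 and 106. Of the 37 called genes named by the rule, 24 and 25 were still called. Genes that lost their call under both scalings included Batf3, Cdkn1c, E2f6, Gja1, Ifitm1, Lbx2, Rfc4, Zbp1 and Zfp42. The call was lost by Fabp6, Gm2a and Selp under median-of-ratios scaling only, and Dppa3 and Rfpl4 under quantile normalization only. With the spread taken from the 2-cell libraries alone, 3 genes were called, 2 of them among the 368. Genes at an unadjusted limma p under 0.05 then fell from 3212 to 1664. The number of calls depended on single libraries: 314 without Tet3-null replicate 2, 3453 without Tet3-null replicate 1, 28 without wild-type replicate 1 and 10 without wild-type replicate 2. Defb13 had a log2 change of 2.93 to 3.31 in these 4 fits. It reached the expression filter only through the Tet3-null 2-cell libraries. All other libraries listed it at 0 and so added no spread to its test. Among 10 other alternatives it was called in 9, with a highest adjusted p of 0.338. Lgals1, Lgals3, Gata2 and Kcne3 were each called in 8 of the 10. Their highest adjusted p was 0.338 for Lgals1 and 0.376 for Lgals3, Gata2 and Kcne3. By size alone, 812 genes differed by at least 1 on the log2 scale without overlap, 164 higher and 648 lower, against 154 and 255 genes for the other 2 splits of the same libraries. Without Tet3-null replicate 1 that count was 2058. The split by direction was 358 and 365 under median-of-ratios scaling and 351 and 385 under quantile normalization. Without a size limit, 47.5% of genes did not overlap between groups, where chance gives 33.3% on average. As genes vary together, this share alone is no test of genotype.

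Of the 19 lists, 2 were called at the 2-cell stage, both upward. Oocyte and maternal-effect genes were higher as a group (median log2 change 0.30, or 0.47 above the median of all genes; 31 of 44 members positive; adjusted p = 7.31e-07), a call lost with an estimated correlation (adjusted p = 0.875 with an estimated correlation). The median was 0.17 without Tet3-null replicate 2, the library that stood apart (adjusted p = 0.0383), and 0.47 without Tet3-null replicate 1 (adjusted p = 1.31e-07). The mean log2(FPKM + 1) of the list was 5.56 and 5.96 in the Tet3-null libraries and 5.62 and 5.38 in wild-type. Dppa3 and Rfpl4, an oocyte-specific RING finger gene, were the members called over all genes; Rfpl4 was at 923 ± 183 against 418 ± 23.6 FPKM. Adjusted over the list alone, 3 members were higher, the third being Cnot7, a subunit of the deadenylase that removes maternal mRNA, at 173 ± 32.8 against 94.8 ± 10.99 FPKM. The 2-cell-stage genes, which are switched on with the zygotic genome, had 22 of 34 members positive (median 0.19, or 0.37 above all genes; adjusted p = 0.00223), with no member called and adjusted p = 0.875 with an estimated correlation. Zscan4e was at 1.75 ± 0.104 against 0.720 ± 0.315 FPKM, Tcstv3 at 381 ± 33.0 against 259 ± 42.0 and Tdpoz3 at 3.98 ± 0.114 against 5.50 ± 0.194. This call was lost without Tet3-null replicate 2 (median 0.05, adjusted p = 0.191), the library that stood apart, and without wild-type replicate 2 (median 0.07, adjusted p = 0.0857).

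The other 17 lists were not called as groups at the 2-cell stage (adjusted p = 0.484 to 0.721), but several held genes that changed. Of 33 trophectoderm genes, 4 fell and 1 rose over all genes, and 6 and 1 did so adjusted over the list alone (median -0.29, or -0.12 relative to all genes). The fallers included Lgals3, Gata2 and Gm2a, a ganglioside activator at 83.6 ± 24.3 against 191 ± 3.42 FPKM, and the riser was Gata3, named here after its value was seen, at 9.26 and 12.3 against 5.28 and 5.26 FPKM. Of 42 imprinted genes, 2 fell, and 5 adjusted over the list alone (median -0.26): Cdkn1c, a maternally expressed inhibitor of cyclin-dependent kinases, was at 9.31 ± 3.78 against 28.3 ± 1.91 FPKM, and Impact, a paternally expressed regulator of translation, at 6.35 ± 1.11 against 19.4 ± 2.89. Of 17 interferon genes, Zbp1 and Ifitm1 fell (median -0.44; 3 lower and 1 higher adjusted over the list alone), the first from 3.62 ± 1.04 to 0.686 ± 0.291 FPKM. Of 43 genes in the list of germline genes under promoter methylation, 1 fell, Tex19.2, from 8.48 ± 0.332 to 2.43 ± 0.445 FPKM, and 4 were lower adjusted over the list alone (median -0.10). The list was not silent at this stage, with a mean log2(FPKM + 1) of 3.68 to 3.83 in the 2-cell libraries.

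Of 50 DNA replication genes, 1 rose and 1 fell (median -0.22; 1 and 3 adjusted over the list alone): Rpa3, a subunit of the single-strand DNA-binding complex, was at 101 ± 1.09 against 61.5 ± 2.85 FPKM, and Rfc4, of the clamp loader, at 7.41 ± 2.26 against 15.9 ± 0.910. Of 28 epiblast and pluripotency genes, Zfp42 fell from 46.5 ± 5.99 to 26.5 ± 2.34 FPKM (median -0.29), and of 6 cumulus and granulosa markers, Gja1, the gap junction gene connexin 43, fell from 86.3 ± 3.36 to 57.1 ± 0.747 (median -0.41). Each was also the only member called when adjusted over the list alone. No member was called over all genes in the lists of chromatin modifiers (median -0.27), ribosome biogenesis and early embryonic transcription (-0.31), glycolysis (-0.29), p53 targets and apoptosis (-0.21; 1 higher and 3 lower adjusted over the list alone), mitosis (-0.20), primitive endoderm (-0.13), blood and other somatic cells (-0.15; 1 lower adjusted over the list alone), sperm (-0.05; 1 higher and 2 lower adjusted over the list alone) and X inactivation and Y-linked genes (-0.68). The ribosome list passed downward without Tet3-null replicate 1 (median -0.52, adjusted p = 0.0104). Without Tet3-null replicate 2 the median turned to 0.03 for mitosis and moved to -0.21 for X inactivation and Y-linked genes, and without Tet3-null replicate 1 these were -0.48 and -1.12. The germline median turned to 0.0046 without wild-type replicate 2, to 0.13 with median-of-ratios scaling and to 0.02 with quantile normalization. In these 2 scalings the median was 0.04 and -0.10 for mitosis, and -0.02 and 0.05 for primitive endoderm. With median-of-ratios scaling it was -0.05 for chromatin modifiers, -0.07 for the ribosome list and -0.06 for glycolysis. It was then -0.09 for p53 targets and -0.03 for DNA replication.

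**Figure D3:**
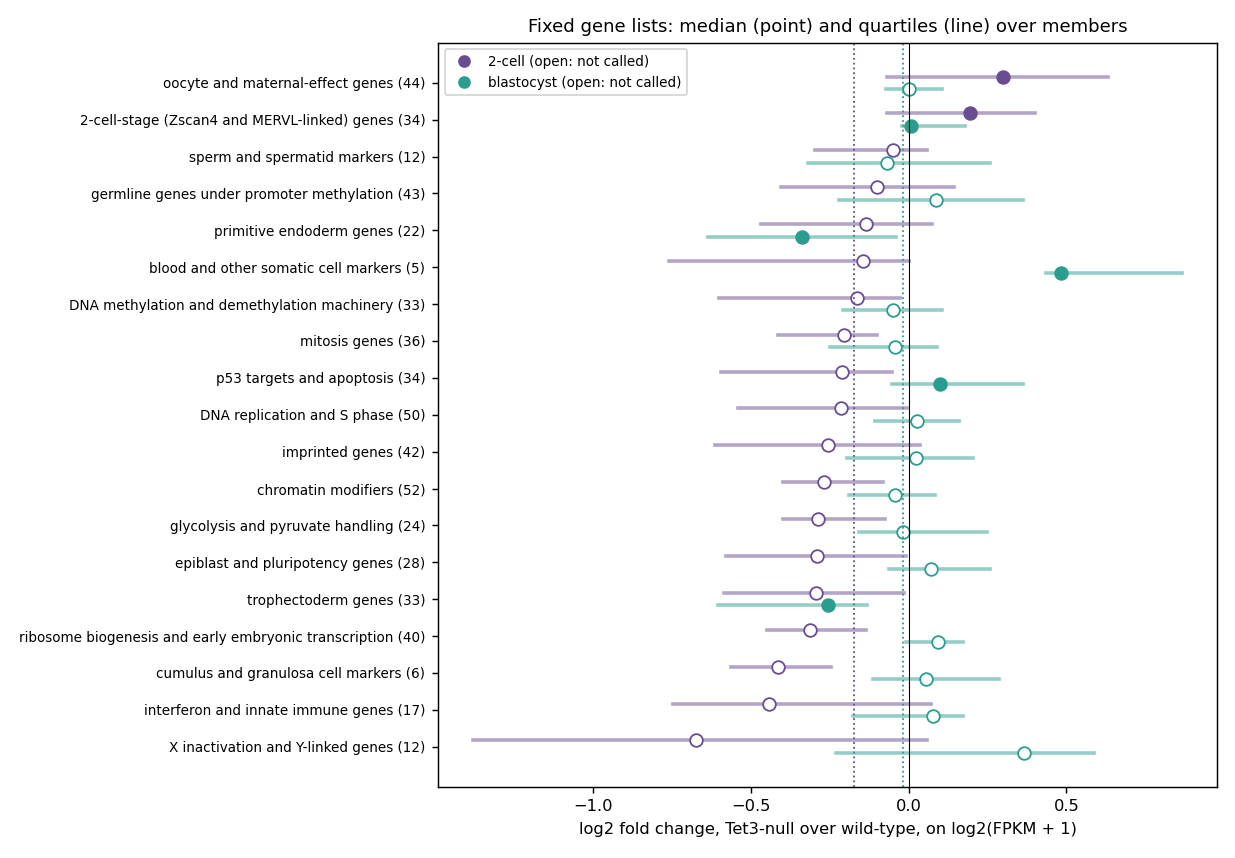
Median log2 change, Tet3-null over wild-type (points, filled where the list was called), and quartiles over members (lines) for the 19 lists at the 2-cell stage and in blastocysts, with the number of genes tested in brackets and the median of all genes as dotted lines. Oocyte genes lay at 0.30 in 2-cell embryos and trophectoderm genes at -0.25 in blastocysts.

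Sex-linked transcripts differed between libraries. The 7 Y-linked genes tested summed to 31.7 FPKM in Tet3-null 2-cell replicate 1 and to 0.166 in replicate 2, against 48.5 and 49.1 in wild-type. Eif2s3y, a Y-linked translation factor gene, was at 18.6 and 0.0952 FPKM in Tet3-null and at 21.6 and 25.6 in wild-type. In blastocysts the sum was 1.88-fold higher in Tet3-null, at 102 and 94.5 FPKM against 54.8 and 49.7, and all 7 genes were higher in both Tet3-null libraries than in both wild-type libraries. Xist, the RNA that coats the inactive X chromosome of female cells, was at 6.36 and 4.64 FPKM in Tet3-null blastocysts and at 16.6 and 14.6 in wild-type, a 2.84-fold difference (adjusted p = 0.260). No Y-linked gene nor Xist was called, and the list of X inactivation and Y-linked genes was not called in blastocysts (median 0.36, adjusted p = 0.931; 2 lower adjusted over the list alone), but it passed with the spread estimated without Tet3-null 2-cell replicate 2 (adjusted p = 0.0474), the library with almost no Y-linked transcripts. The median log2 change of 506 X-linked genes was 0.03 in 2-cell embryos, against -0.18 for autosomal genes, and -0.05 against -0.02 in blastocysts.

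**Figure D4:**
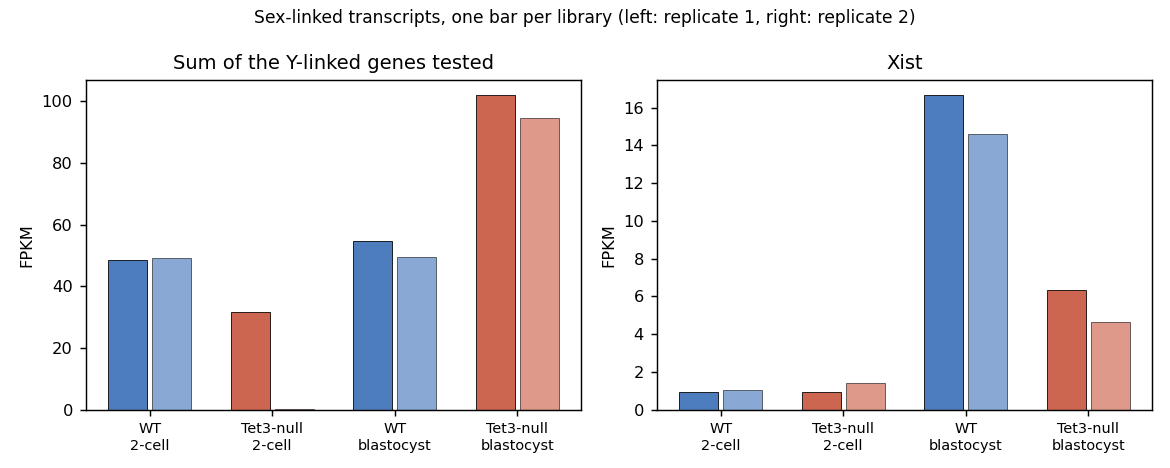
Summed FPKM of the 7 Y-linked genes tested (left) and FPKM of Xist (right), one bar per library. Tet3-null 2-cell replicate 2 had 0.166 FPKM of Y-linked transcripts, and Tet3-null blastocysts had 102 and 94.5 against 54.8 and 49.7 in wild-type.

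In blastocysts few genes were called. Hprt, the X-linked purine salvage enzyme, rose 4.58-fold in Tet3-null blastocysts, from 330 ± 66.5 to 1511 ± 59.9 FPKM (log2 change 2.21, SE 0.18, adjusted p = 0.00829), and was the only call outside small RNA genes. The other 8 of the 9 calls (2 higher, 7 lower) were small RNA genes that were all or none, such as Mir142, at 0 in both Tet3-null libraries and at 223 and 197 FPKM in wild-type, and Mir1894, at 40.7 and 41.6 against 0. Both were chosen here after their values were seen. At an unadjusted p under 0.05 there were 740 genes in the limma fit, 1334 with the spread estimated without Tet3-null 2-cell replicate 2 and 1821 in the blastocyst libraries alone. Without regard to size, 44.2% of genes did not overlap between groups, where chance gives 33.3% on average, which is no test of genotype either. By size alone, 110 genes differed by at least 1 on the log2 scale without overlap, 38 higher and 72 lower, against 55 and 46 for the other splits. Hprt stayed called without wild-type replicate 2 (adjusted p = 0.0296) and was lost without wild-type replicate 1 (0.0719), Tet3-null replicate 1 (0.132) or Tet3-null replicate 2 (0.107). It was also lost with no filter (0.0640) and in the blastocyst libraries alone (0.219). By size alone the count was 179 and 190 genes without Tet3-null replicate 1 or 2, and 185 and 226 without wild-type replicate 1 or 2.

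The next genes by the rule did not pass. Higher values in Tet3-null blastocysts were measured for Tmsb15b1, a thymosin, at 5.69 ± 0.0666 against 2.06 ± 0.164 FPKM (adjusted p = 0.180), Cd81, an imprinted tetraspanin, at 143 ± 16.3 against 82.5 ± 5.09, Sct, the hormone secretin, at 123 ± 5.31 against 70.3 ± 3.31, Cox6b2 at 240 ± 8.08 against 154 ± 11.9, and at lower levels Trim40, Krt14, Calb2, Ostm1 and Pvrl4. Lower values were measured for Lama1, a laminin chain of the basement membrane, at 1.12 ± 0.256 against 4.46 ± 0.129 FPKM (adjusted p = 0.135), the water channel gene Aqp8 at 14.1 ± 2.95 against 35.0 ± 2.57, the initiation factor gene Eif1 at 155 ± 11.8 against 272 ± 24.0, Rabac1 at 84.0 ± 4.02 against 154 ± 22.4, Cisd1 at 40.1 ± 2.59 against 76.9 ± 8.65, and Xlr4a, Hpdl, Pgrmc1 and H2-D1.

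Trophectoderm genes, of the outer layer that forms the placenta, were lower as a group in Tet3-null blastocysts (27 of 33 members negative, median -0.25, adjusted p = 3.45e-07; adjusted p = 0.0602 with an estimated correlation). The estimated correlation of the list was 0.00127, below the preset 0.01, so a higher correlation was not why its p-value rose. Adjusted over the list alone, 2 members fell and 0 rose. These were Gata2, at 28.7 ± 1.75 against 49.3 ± 1.40 FPKM (1.72-fold), and Krt8, an epithelial keratin, at 549 ± 31.1 against 1018 ± 84.4 (1.85-fold). Atp1b1, a subunit of the sodium pump, was at 20.1 ± 0.346 against 33.4 ± 3.31. The list stayed called in each fit with a blastocyst library left out (median -0.38 to -0.23). Primitive endoderm genes were also lower as a group (17 of 22 negative, median -0.34, adjusted p = 0.000154; adjusted p = 0.333 with an estimated correlation). Their median was -0.14 with no filter (adjusted p = 0.000644) and -0.21 with a filter at 5 FPKM (adjusted p = 0.0334). Lama1 and Serpinh1, the collagen chaperone, at 5.56 ± 1.89 against 16.6 ± 5.13 FPKM, were lower adjusted over the list alone, and Cubn, an endocytic receptor, was at 0.558 ± 0.0504 against 1.19 ± 0.0646. Epiblast and pluripotency genes were not called (17 of 28 positive, median 0.07, adjusted p = 0.0926), and passed without Tet3-null replicate 1 (median 0.22, adjusted p = 1.95e-05) or wild-type replicate 1 (0.18, adjusted p = 0.00667). Klf5 was at 87.5 ± 9.37 against 130.5 ± 16.6 FPKM, Tbx3 at 28.3 ± 0.0694 against 23.0 ± 3.04 and Fbxo15 at 494 ± 4.55 against 377 ± 42.8. Y-linked transcripts were higher and Xist lower in the same libraries, as given above.

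**Figure D5:**
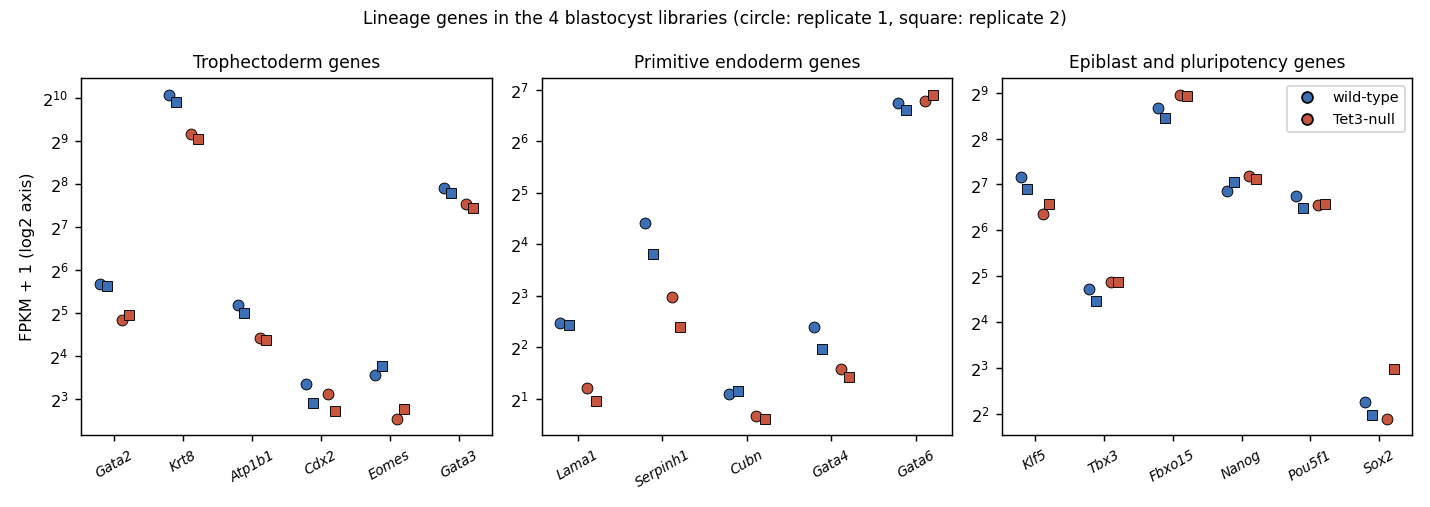
FPKM + 1 on a log2 axis of trophectoderm, primitive endoderm and epiblast genes in the 4 blastocyst libraries, one point per library. Cdx2, Eomes, Gata3, Gata4, Nanog, Pou5f1 and Sox2 were added as well-known lineage genes after their values were seen. Krt8 was at 549 against 1018 FPKM and Lama1 at 1.12 against 4.46 in Tet3-null and wild-type, and no gene shown was called over all genes.

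Among lineage genes, the trophectoderm factor Eomes was at 4.83 and 5.82 FPKM in Tet3-null against 10.9 and 12.7 in wild-type (adjusted p = 0.638). Cdx2 was at 7.79 and 5.67 against 9.21 and 6.595, and Gata3 at 184 and 172 against 240 and 221. The primitive endoderm factor Gata6 was at 109 and 119 against 107 and 96.4, and Gata4 at 1.97 and 1.68 against 4.23 and 2.91. The pluripotency factor Nanog was at 145 and 138 against 114 and 132, Pou5f1 at 92.7 and 93.9 against 107 and 88.3, and Sox2 at 2.68 and 6.89 against 3.75 and 2.89.

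Another 3 lists were higher as groups in Tet3-null blastocysts at the preset correlation. Of 20 markers of blood and other somatic cells, 5 reached the expression filter, and all 5 were positive (median 0.48, adjusted p = 1.92e-05; adjusted p = 0.0794 with an estimated correlation). Krt14, a keratin of basal epithelia, at 3.77 ± 1.73 against 0.642 ± 0.309 FPKM, and Hba-a2, an alpha globin, at 2.04 ± 0.660 against 0.662 ± 0.308, were higher adjusted over the list alone. The estimated correlation of this list was -0.0931, also below the preset 0.01. Krt14 reached the filter only through the Tet3-null blastocysts. The filter thus partly picked members that were high there, and the shared sign of the 5 is not independent support. The median of the list was 0.0130 with no filter (adjusted p = 0.0395) and 0.31 without wild-type replicate 2 (adjusted p = 0.000168). Of p53 targets and apoptosis genes, 25 of 34 were positive (median 0.10, adjusted p = 0.00161; adjusted p = 0.354 with an estimated correlation), with none called over all genes or over the list alone. The median was 0.03 without Tet3-null replicate 1 (adjusted p = 0.0475) and 0.19 without Tet3-null replicate 2 (adjusted p = 0.000277). Bid, which links death receptors to mitochondria, was at 22.5 ± 1.20 against 12.9 ± 2.04 FPKM and Phlda3, an inhibitor of Akt, at 7.97 ± 0.516 against 5.28 ± 0.419. Of 2-cell-stage genes, 18 of 34 were positive (median 0.01, adjusted p = 0.0334; adjusted p = 0.458 with an estimated correlation), among them Arg2 at 5.04 ± 1.40 against 2.32 ± 0.668 and Sp110 at 106 ± 4.44 against 70.4 ± 11.9. This call was lost under quantile normalization (adjusted p = 0.152) and median-of-ratios scaling (0.0832), with no filter (0.0644), with the spread estimated without Tet3-null 2-cell replicate 2 (0.0660), and without Tet3-null replicate 2 (0.0732) or wild-type replicate 2 (0.0651).

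The remaining lists were not called in blastocysts, but 4 of them passed in some alternative fits. Medians were 0.09 for ribosome biogenesis and early embryonic transcription (adjusted p = 0.0582), 0.09 for germline genes (0.0716), -0.0003 for oocyte genes (0.0728), 0.05 for cumulus and granulosa markers (0.126), 0.08 for interferon genes (0.170), 0.03 for DNA replication and -0.02 for glycolysis (0.352 each), -0.04 for mitosis (0.352), 0.02 for imprinted genes and -0.04 for chromatin modifiers (0.526 each), and -0.07 for sperm markers (0.615). Ribosome genes passed with a pseudocount of 0.1 (adjusted p = 0.0436), median-of-ratios scaling (0.0137), without X-linked and Y-linked genes (0.0425), with the spread estimated without Tet3-null 2-cell replicate 2 (0.0186), and without Tet3-null replicate 1 (0.0475) or wild-type replicate 1 (0.0302). Germline genes passed with that same spread (0.0474) and without Tet3-null replicate 1 (0.00960) or wild-type replicate 2 (0.0362). Oocyte genes passed without Tet3-null replicate 2 (0.0276) or wild-type replicate 2 (0.0384), and mitosis genes passed without wild-type replicate 1 (0.0369). Adjusted over the list alone, Hsd17b1, an enzyme of estradiol synthesis, was higher at 16.95 ± 1.93 against 7.90 ± 1.76 FPKM, as was 1 imprinted gene, with 1 other lower. Hormad1, a meiotic chromosome axis gene, was at 43.0 ± 0.456 against 24.0 ± 3.84 FPKM without passing.

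The effect of genotype differed between the stages for 19 genes, 13 of them small RNA genes. Defb13 was higher in Tet3-null at the 2-cell stage and listed at 0 in all blastocyst libraries (difference of log2 changes -3.12, adjusted p = 0.00619). Another 5 genes were lower in Tet3-null 2-cell embryos and not lower in blastocysts. Calb2, the calcium buffer calretinin, was listed at 0 in Tet3-null and at 2.42 ± 0.643 FPKM in wild-type 2-cell embryos, and at 5.83 ± 0.531 against 2.29 ± 0.461 in blastocysts (difference 2.82, adjusted p = 0.0243). Ergic3, of transport between the endoplasmic reticulum and Golgi, was at 12.5 ± 2.53 against 49.9 ± 0.00778 FPKM and then at 185 ± 1.31 against 168 ± 0.176 (2.06, adjusted p = 0.0271). The others were Fcgrt, the neonatal Fc receptor (2.31), Tmsb15b1 (1.99) and Kcne3 (2.84), each with an adjusted p of 0.0330. Without small RNA genes in the fit only Defb13 passed (adjusted p = 0.0447), and Calb2, Ergic3, Fcgrt, Tmsb15b1 and Kcne3 did not (0.0704 each). Of 16 alternative fits, Defb13 passed in 10, Calb2 and Ergic3 in 8, Fcgrt and Tmsb15b1 in 6 and Kcne3 in 5. Lgals1 (2.18, adjusted p = 0.0543) and Tppp3 (2.98, adjusted p = 0.0554) did not pass. The count was 1703 without Tet3-null 2-cell replicate 1 and 42 without Tet3-null 2-cell replicate 2, and 13 to 20 with any other library left out.

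Across genes the genotype effects at the 2 stages were unrelated (Pearson's r 0.00906; genes are not independent replicates). Among the 368 and 9 calls, 1 gene was shared, where independent lists of that size share 0.244. For 3 lists the effect differed between stages at the preset correlation: oocyte and maternal-effect genes (median difference -0.24, adjusted p = 0.00581), blood and other somatic markers (1.20, adjusted p = 0.0360) and primitive endoderm genes (-0.01, adjusted p = 0.0361). With an estimated correlation the adjusted p was 0.645, 0.588 and 0.588. The primitive endoderm median lay near 0 although the test was downward, with 11 of 22 members negative and a mean of -0.21. The call of oocyte genes was lost without Tet3-null (adjusted p = 0.334) or wild-type (0.0947) 2-cell replicate 2. That of blood and other somatic markers was lost without any 1 of the 2-cell libraries, with adjusted p-values of 0.155 and 0.0619 for Tet3-null replicates 1 and 2 and of 0.0953 and 0.0613 for wild-type, and with no filter (0.0618). That of primitive endoderm genes was lost without the same Tet3-null libraries (0.125 and 0.0619), wild-type 2-cell replicate 2 (0.0984) or wild-type blastocyst replicate 1 (0.139), and with a pseudocount of 0.1 (0.264), no filter (0.0618), a filter at 5 FPKM (0.192) or median-of-ratios scaling (0.127).

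From the 2-cell stage to the blastocyst, 10064 genes changed in wild-type, 4857 upward and 5207 downward. In Tet3-null 10028 changed, 5276 upward and 4752 downward. Median-of-ratios scaling gave 4801 upward and 5175 downward in wild-type and 4963 and 5136 in Tet3-null. Quantile normalization gave 4927 and 4927 in wild-type and 5076 and 4892 in Tet3-null. The balance of rises and falls thus depended on scaling. The genes with the largest rises in wild-type included Fabp3, a fatty acid-binding protein, from 15.5 ± 2.86 to 7561 ± 789 FPKM (486-fold), Krt18, the partner keratin of Krt8, from 10.5 ± 1.94 to 3052 ± 121 (291-fold), the tight junction gene Cldn4 from 1.58 ± 0.519 to 523 ± 55.5, the alcohol dehydrogenase gene Adh1 from 0.939 ± 0.503 to 602 ± 68.6, Sdc4 from 7.09 ± 1.05 to 1322 ± 5.82, and Ass1, Fbp2, Cryab, Capg and Fxyd4. The largest falls were in oocyte transcripts. Omt2b fell from 7288 ± 134 to 0.0536 ± 0.0758 FPKM, Omt2a from 7556 ± 22.2 to 0.235 ± 0.214, and Btg4, the adaptor that brings the deadenylase to maternal mRNA, from 2179.7 ± 331 FPKM to listed at 0, with Oog3, Obox5, Oosp1, Obox3, C86187, Tcl1b1 and Tcl1b2 also among the 10.

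Of 44 oocyte and maternal-effect genes, 40 fell and 2 rose with stage in wild-type and 42 fell and 2 rose in Tet3-null. All but 3 of the 34 2-cell-stage genes fell in each genotype; Zfp352 dropped from 361 ± 23.0 to 0.357 ± 0.0156 FPKM in wild-type. Of 33 trophectoderm genes, 27 rose in each genotype, and 4 fell in wild-type and 3 in Tet3-null. Of 22 primitive endoderm genes, 18 rose in wild-type and 16 in Tet3-null, led by Lrp2, an endocytic receptor (log2 change 5.50), Gata6 (5.41) and Dab2 (4.67). Of 28 epiblast genes, 11 rose and 7 fell in wild-type and 15 rose and 5 fell in Tet3-null, with Tdgf1 (log2 change 4.74) and Fgf4 (-3.89) moving apart. Tet2 rose with stage (log2 change 4.72) and Tet3 fell (-2.57) in wild-type. The stage effects of the genotypes correlated across genes (r = 0.947), and 8921 genes were called in the same direction in both, against 16 in opposite directions.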

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

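The difference of genotype effects between stages was a planned comparison, and the fit without small RNA genes and all tests of explanations in this part were chosen after the result was seen. For 19 genes the limma contrast of the Tet3-null effect in blastocysts minus that in 2-cell embryos passed. Outside small RNA genes these were Defb13 (log2 difference -3.12), Calb2 (2.82), Ergic3 (2.06), Fcgrt (2.31), Tmsb15b1 (1.99) and Kcne3 (2.84). Without small RNA genes in the fit, 1 gene passed, Defb13 (adjusted p = 0.0447), and the other 5 of these did not (adjusted p = 0.0704 each). At the preset correlation the same contrast passed for 3 lists, with a median difference of -0.24 for oocyte and maternal-effect genes, of 1.20 for blood and other somatic markers and of -0.0136 for primitive endoderm genes. None of these passed with an estimated correlation (adjusted p = 0.645, 0.588 and 0.588 in this order).

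Y-linked transcripts were near 0 in Tet3-null 2-cell replicate 2. Loss of weakly expressed genes from a thinner library is unlikely to be the reason, since only 3.52% of 4007 autosomal genes of matched level were under 5% of their level in the other 2-cell libraries. A pool without male embryos stays open, since the summed Y-linked signal of 0.386% of the mean of the other 2-cell libraries is the pattern itself and no separate test of it; 10 embryos would all be female by chance with a probability of 0.000977. Embryos that lacked a sperm genome could not be told apart from this by Xist. Its value was 144% of its mean in the other libraries, but that mean was low (0.979 FPKM). Reads of Tsix also cannot be separated from those of Xist in these libraries. The protocol kept zygotes with 2 pronuclei.

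Oocyte and maternal-effect genes were higher as a group in Tet3-null 2-cell embryos at the preset correlation. A trend with expression level is unlikely to explain this, as the list median lay at percentile 100 of 10000 random lists matched on mean expression, whose medians centred on -0.12. Whether the shift rests on replicate 2 alone stays open. Without that library the list median was 0.30 above that of all genes and passed at the preset correlation (adjusted p = 0.0383), but with all libraries it did not pass with an estimated correlation (0.875). Relative to all genes, replicate 1 lay 0.13 and 0.36 above the wild-type libraries, which differed from each other by 0.24. Collection at an earlier point of development may contribute but could not be judged: genotype and stage effects from separate wild-type libraries correlated at r = -0.0746 and -0.152, and along the stage axis the Tet3-null libraries lay further apart (0.0263) than the genotypes (0.0132).

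Xist was lower and Y-linked genes were higher in Tet3-null blastocysts. Fewer female embryos in the Tet3-null pools of 7 stay open, since the median ratio of Y-linked genes of 2.06 is part of the pattern and no separate test. A change of Xist alone at equal sex makeup would not raise Y-linked genes, of which 7 of 7 were higher in both Tet3-null libraries. As that rise is also part of the pattern, it is no separate test of this explanation. A difference in sex makeup that depends on the genotype was not tested, nor was its effect on other differences between the blastocyst groups.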

How the results depend on the processing

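Most alternatives were chosen beforehand, and 3 were added after the results were seen: leaving out small RNA genes, leaving out X-linked and Y-linked genes, and a spread estimated without Tet3-null 2-cell replicate 2. The log2 change of Tet3 at the 2-cell stage ranged from -1.29 to -0.83 without passing. A pseudocount of 0.1 gave 243 calls at the 2-cell stage and, by the size rule, 1861 genes at the 2-cell stage and 509 in blastocysts, because a smaller pseudocount widens differences of weakly expressed genes. With no filter, 35 genes and 1 list differed between stages, and with a filter at 5 FPKM 1 list did; the cause was not tested. The blood list has no value at 5 FPKM, as fewer than 5 members remain. Quantile normalization gave 194 calls at the 2-cell stage and turned the log2 change of Dnmt1 to 0.11, Dnmt3a to 0.0858, Dnmt3l to 0.0550, Uhrf1 to 0.0332 and Tdg to 0.0250. Median-of-ratios scaling gave 163 calls and turned Dnmt1 to 0.13, Dnmt3a to 0.11, Dnmt3l to 0.13 and Uhrf1 to 0.10 at the 2-cell stage, and Dnmt3l to 0.0328 and Uhrf1 to 0.00262 in blastocysts. Both scalings remove the shift of all genes, so small negative changes turn positive. The 2-cell libraries alone gave 3 calls and the blastocyst libraries alone gave 6. Genes at an unadjusted limma p under 0.05 then numbered 1664 at the 2-cell stage and 1821 in blastocysts. In the joint fit they numbered 3212 and 740. The contrast of 368 and 9 calls thus depended on a spread shared between the stages. Fits of 1 stage also have fewer degrees of freedom, and the part played by each was not tested. Same-numbered libraries showed no shared deviation (correlation of deviations -0.076 at the 2-cell stage and 0.018 in blastocysts). With 2 libraries a group this cannot exclude a shared collection, which the labels leave open. A fit with replicate number as a block gave 7 calls at the 2-cell stage and 12 for the difference between stages. In that block fit the adjusted p was 0.152 for Dppa3 at the 2-cell stage, 0.107 for Hprt in blastocysts and 0.0697 for 2-cell-stage genes in blastocysts. With an estimated correlation 0 lists were called at the 2-cell stage, 0 in blastocysts and 0 for the difference between stages. The medians were the same by construction, at 0.30 for oocyte genes, 0.19 for 2-cell-stage genes, -0.34 for primitive endoderm and -0.25 for trophectoderm. Without small RNA genes there were 584 calls at the 2-cell stage, 1 in blastocysts and 1 for the difference between stages. In blastocysts the 8 calls lost were the small RNA genes themselves; for the other counts the cause was not tested. Fits with a library left out rest on a lone library in 1 group, assumed to vary like the other groups; why a given library moved a count was not tested. Across them, calls ranged from 10 to 3453 at the 2-cell stage and from 13 to 1703 for the difference between stages. The size rule gave 699 to 2058 genes at the 2-cell stage and 179 to 226 in blastocysts. From 1 to 3 lists were called at the 2-cell stage, 5 to 8 in blastocysts and 0 to 4 for the difference. In the same fits the log2 change at the 2-cell stage ranged from -0.0614 to 0.191 for Tet2, -0.261 to 0.0304 for Dnmt3a, -0.245 to 0.0164 for Dnmt3l and -0.513 to 0.239 for Uhrf1. In blastocysts it ranged from -0.418 to 0.00496 for Tet3, -0.100 to 0.235 for Tet1, -0.0438 to 0.146 for Dnmt1 and -0.0459 to 0.00556 for Dnmt3l. List medians ranged from 0.0479 to 0.318 for 2-cell-stage genes and from -0.524 to -0.0618 for ribosome biogenesis at the 2-cell stage, and from -0.0554 to 0.222 for epiblast genes in blastocysts. The ribosome list passed downward without Tet3-null replicate 1, while the direction of its test turned without replicate 2. Since read totals are unknown, genes near 0 FPKM cannot be told from genes that were not sampled.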

Other observations

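Some called genes of the 2-cell stage outside the naming rule were chosen after their values were seen. Tcl1b2, of an oocyte-expressed family, was at 983 ± 79.9 FPKM in Tet3-null against 554 ± 54.9 in wild-type 2-cell embryos (adjusted p = 0.0429). Rabac1, a regulator of vesicle transport, was 2.29-fold lower, at 23.9 ± 0.239 against 54.6 ± 1.94 FPKM (adjusted p = 0.0229), and Sct, the hormone secretin, was at 5.59 ± 0.215 against 11.5 ± 1.73 (adjusted p = 0.0382).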
